A study of Homo sapiens with 51 samples.

How the data were processed

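Accessible chromatin was measured by ATAC-seq, in which a transposase inserts sequencing adapters into open DNA. The cells were H1, an established human embryonic stem cell (hESC) line, in 3 genotypes labelled WT, KO and ΔATG (DATG in the sample names). The labels do not name the edited gene, so no edit could be checked at a named gene. Libraries were made with the Active Motif ATAC kit and amplified by PCR, per the labels' protocols. The samples were undifferentiated cells at day 0, cells under BMP4, which the labels call mesoderm, and cells under a treatment labelled SMADi, which they call neuroectoderm.

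The deposited values were 3 tables of counts, whole numbers of reads in 201-bp regions of GRCh38 that were not normalized. The submitters' processing notes name MACS2, a peak caller, and the build. The aligner, the peak settings, the duplicate handling and any shift of reads for the transposase are not given in the sources used here. Each table had its own region set, with 100584 regions at day 0, 142087 under BMP4 and 162317 under SMADi. Tests were therefore run only within a table, and day 0 was never tested against a later day.

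The 51 libraries comprised 18 WT, 17 KO and 16 DATG libraries, with replicates lettered a and b. BMP4 covered days 1 to 5 with 2 libraries per genotype and day. SMADi days 2 and 3 are not analysed here, and KO day 4, DATG day 1 and DATG day 5 under SMADi had 1 library each. A group with 1 library entered tests with the spread shared by its table. The labels do not say that replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. Every replicate pair differed by more than sampling noise in a chi-square test over regions, and all were counted as separate libraries. With so many regions this test passes at a small excess. Chi-square per degree of freedom ran from 1.03 (KO day 1 BMP4) to 3.15 (WT day 5 SMADi), so the test does not show separate preparations.

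Total counts per library were 4616521 to 7516259 at day 0, 4019778 to 13850448 under BMP4 and 7086918 to 23252871 under SMADi. The median biological coefficient of variation was 0.0844, 0.0756 and 0.138 in the same order. Simulated counts with the means, depths and spread of the real tables, with 200 of 20000 regions changed, tested the procedure on KO against WT. Of regions changed by 1 on the log2 scale, 58% were recovered at day 0, 99% under BMP4 and 92% under SMADi. Of those changed by 0.5, the test recovered 8%, 70% and 34%, so small changes at day 0 were mostly not detectable with 2 libraries per line. False calls numbered 4, 10 and 3. PCR reads without molecular identifiers are not independent molecules, so floors and intervals cover counting error only.

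Before the data were examined, groups, tests, alternatives and gene lists were fixed. The test was edgeR's quasi-likelihood F test (edgeR 4.0.16, R 4.3.3) with TMM scaling, filterByExpr, robust spread estimates and 1 mean per genotype and day. The filter left 100582, 142083 and 162313 regions. Regions with a Benjamini-Hochberg adjusted p under 0.05 were called, and "higher", "lower", "rose" and "fell" are used of such calls. Genotype effects were the mean over days of within-day differences, differentiation was day 5 against day 1, and the interaction was the day 5 against day 1 change of a mutant line minus that of WT. Fold changes are given on the log2 scale with a standard error (SE). The SE was back-calculated as the absolute log2 fold change divided by the square root of F, so it is approximate where a group had few counts.

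Genes came from RefSeq on GRCh38.p14, with 38151 genes used, 19974 of them protein-coding and 18177 lncRNA. The annotation held no strand, so the planned distance to a gene start was replaced by the distance to the nearer annotated gene end, and "near a gene end" means within 1 kb of either end. For gene-linked values, counts were summed over regions whose nearest gene end lay within 50 kb and tested in the same way. The 17 lists held 363 distinct genes, all matched by symbol, with TDGF1 matched under its current symbol CRIPTO. They covered pluripotency, primitive streak and nascent mesoderm, lateral plate and cardiac mesoderm, endoderm, amnion and trophoblast, targets of BMP, Nodal and Activin, WNT and p53, neuroectoderm, neural crest and placode, endothelial and blood, mesenchyme and fibroblast, epithelial, HOX and CDX, imprinted genes, and ribosomal protein genes as a control. Lists shared members, for example MSX2 and DLX5 in 3 of them. Lists were tested with limma's camera (limma 3.58.1, two-sided) at a preset inter-gene correlation of 0.01, adjusted over the 17 lists, and again with the correlation estimated per list.

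Named regions were the 5 strongest called regions in each direction among those at or above the median log2 CPM with a protein-coding gene end within 50 kb, 1 region per gene. Some of these named regions and list members are not reported here. CPM here is a library's counts scaled to a common total, computed from the deposited counts. Named list members were up to 2 with the lowest adjusted p in each direction. Which list and comparison pairs to describe was chosen after the tests were seen. Genes POU5F1, NANOG, TBXT, GATA6, HAND1, PAX6, SOX1 and SOX17 were fixed as anchors. Where a group had 0 counts in every library, a fold is a bound computed against a floor of 3 counts per library.

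The position of a library between WT day 1 and WT day 5 was its mean log2 CPM over regions that WT opened minus that over regions WT closed, scaled so that WT day 1 was 0 and WT day 5 was 1. These regions changed by more than 1 on the log2 scale in 1 WT replicate and were read against the other, in both directions. WT values at days 1 and 5 have no spread by construction, and position differences are therefore given without a p. A library's position between KO and DATG was computed in the same way over regions called between these lines in another table. The share of zinc-finger genes was tested among called regions near a protein-coding gene end, under BMP4 and SMADi only among calls over 2-fold apart. Fisher's exact tests here count regions, and several regions can lie at the same gene end. Their p-values treat regions as independent and do not measure spread between libraries. Correlations of KO and DATG effects were set beside simulated unchanged groups against the same WT libraries. Alternatives were another scaling, filter, test, block, link distance or list correlation, and each library left out in turn. Equal-depth thinning, days 1 to 4 alone, days with 2 libraries alone, and list, correlation and position values without the library labelled KO day 1 SMADi replicate b were added after the data were seen. DESeq2 1.42.0 was used only as an alternative. Motif tests and GC checks were not run, because no genome sequence was used here.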

Results

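Chromatin accessibility was counted in 51 libraries from WT, KO and ΔATG (DATG) H1 cells, with 18, 17 and 16 libraries respectively. The series concerns an RNA with more than a single function in human embryonic development, and the design followed the lines into mesoderm under BMP4, a growth factor, and into neuroectoderm under SMADi. The comparisons ask what differentiation did in WT cells and where the mutant lines differed from WT before and during it. Depth ran from 4019778 counts in DATG day 5 BMP4 replicate b to 23252871 in the DATG day 5 SMADi library. WT day 5 SMADi replicate a, at 7086918 counts, was the shallowest library of its table. In the library labelled KO day 1 SMADi replicate b, the regions that told the mutant lines apart elsewhere looked like DATG. At regions called between KO and DATG under BMP4 it lay 0.871 of the way from KO to DATG. It was kept as labelled, so SMADi values for KO that cover day 1 include it. The fit shares spread across groups, so this library also bears on the other SMADi tests. DATG against WT had 46241 calls with it and 44577 without it, and the DATG interaction 22518 and 20389.

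At day 0 the KO line had lost accessibility at the ends of several zinc-finger protein genes, which encode DNA-binding proteins. At ZNF667 (chromosome 19, 56477438 to 56477638, 555 bp from a gene end) the log2 fold change was −4.90 ± 0.39 (SE, n = 2 libraries per group, adjusted p = 1.59e-20). KO had 4 and 1 counts there against 105 and 78 in WT. ZNF585A (chromosome 19, 37172729 to 37172929, 134 bp outside the gene) fell by 4.89 ± 0.44 and ZNF354C (chromosome 5, 179060219 to 179060419, 54 bp outside) by 4.08 ± 0.39. ZNF835 and ZNF229 fell by 1.63 ± 0.23 and 1.40 ± 0.23. Regions higher in KO lay 19678 bp from FAM8A1 (2.51 ± 0.34), within STK33, a kinase gene (2.37 ± 0.26), within the lipid transporter gene ABCA7 (2.06 ± 0.22), near LOC124902053 (1.51 ± 0.21) and within CFLAR, a regulator of apoptosis (1.13 ± 0.25, adjusted p = 0.0177). In all, 86 of 100582 regions were called, 54 higher and 32 lower, and 8351 had an unadjusted p under 0.05. Leaving out WT replicate a gave 41 calls and leaving out WT replicate b gave 183, and a DESeq2 Wald test gave 19.

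The DATG line at day 0 had lost a different region, at the end of CHCHD2 (chromosome 7, 56106435 to 56106635, 59 bp outside the gene), a gene for a mitochondrial protein. It fell by 5.79 ± 0.45 (SE, n = 2 per group, adjusted p = 1.07e-21). It held 2 and 1 counts in DATG against 109 and 63 in WT and 72 and 25 in KO. Regions near PARK7, which encodes a protein of the oxidative stress response (−1.95 ± 0.25), CHD9, a chromatin remodeller gene (−1.72 ± 0.25), PRAF2 (−1.55 ± 0.25) and ZNF414 (−1.52 ± 0.23) also fell. Higher regions lay near FAM8A1 (3.11 ± 0.31), DHRS2 (1.10 ± 0.23) and PRRT1 (1.03 ± 0.18). DATG differed from WT at 207 regions, 41 higher and 166 lower, and 15.1% of the lower regions lay near a gene end against 36.2% of tested regions (Fisher's exact p = 1.88e-09). Without WT replicate a the count was 31, and without WT replicate b it was 278. It was 13 with DESeq2, 54 after thinning to equal depth, 64 with loess and 123 with a replicate block.

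Compared directly at day 0, KO and DATG differed at 331 regions, 249 higher in KO and 82 lower. KO was higher at CHCHD2 (5.19 ± 0.50), PRAF2 (2.39 ± 0.23), STK33 (2.04 ± 0.25), PARK7 (2.00 ± 0.26) and USP4, a deubiquitinase gene (1.72 ± 0.23). It was lower at ZNF585A (−5.03 ± 0.43), ZNF667 (−4.68 ± 0.40), ZNF354C (−4.62 ± 0.36), CT47B1 (−1.54 ± 0.27) and ZNF835 (−1.49 ± 0.23). Leaving out KO replicate b gave 123 calls and leaving out KO replicate a gave 261, while DESeq2 gave 38 and thinning 205. Developmental genes showed no such differences: none of the 8 anchor genes passed in either line, for example POU5F1 at −0.20 ± 0.15 in KO and −0.06 ± 0.14 in DATG. Of the 17 lists only epithelial genes passed in KO (adjusted p = 0.032, and adjusted p = 0.855 with an estimated correlation). None of its 16 measured members was called over all genes, 1 was higher adjusted over the list alone, and ESRP1 and EPCAM stood at 0.28 ± 0.09 and 0.17 ± 0.09. The other lists had adjusted p from 0.538 to 0.939 in KO, and no list passed for DATG or for KO against DATG.

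Some of the regions lower at day 0 were also lower under BMP4 and SMADi as means over days. Where a day 0 region overlapped several later ones, the one with the smallest p was taken for the calls in all 3 tables. Of the 86 KO regions from day 0, 28 were called in the same direction in all 3 tables, 18 of them lower, out of 32 lower at day 0. Of those 18, 15 lay near a gene end, and the median log2 fold changes were −3.10 at day 0, −3.66 under BMP4 and −4.04 under SMADi. Without the doubted library 32 regions were called in all 3 tables, 18 of them lower, with a median of −4.62 under SMADi. For DATG 52 of 207 were called in the same direction in all 3 tables, 43 of them lower, out of 166 lower at day 0. Of those 43, 14 lay near a gene end, and the medians were smaller, at −1.50 at day 0, −1.14 under BMP4 and −2.19 under SMADi. Under BMP4 all 10 KO libraries had 0 to 0.637 CPM at ZNF585A, against 7.93 to 11.7 in WT. All 10 DATG libraries had 0 to 0.592 CPM at CHCHD2, against 6.51 to 12.6 in WT. Same signs were seen in 61 of 75 overlapping KO regions under BMP4 (81.3%, exact 95% interval 70.7 to 89.4) and 62 of 80 under SMADi (77.5%, and 63 of 80 without the doubted library). For DATG it was 104 of 172 (60.5%) and 160 of 181 (88.4%). Over all overlapping regions the same-sign shares were 50.5% and 56.5% for KO and 49.3% and 55.2% for DATG. Under BMP4 19 of the DATG regions were called the opposite way, against 67 the same way. Zinc-finger genes made up 10 of 11 KO-lower regions near a protein-coding gene end at day 0, against 2.56% of tested ones (Fisher's exact adjusted p = 1.46e-14 over 12 such tests), a theme chosen after the data were seen. For DATG the number was 0 of 11. Losses at zinc-finger genes were not confined to KO, however. The region 2102 bp from ZNF610 had a mean of 1.5 counts in DATG at day 0 against 30.5 in WT. Near ZNF454 the means were 1.9 in KO and 1 in DATG under BMP4 (46.4 in WT), and 1 and 2 under SMADi (137.5 in WT). Near ZNF671 they were 1.4 and 2.25 under SMADi (35.83 in WT). Among regions over 2-fold lower, zinc-finger genes were 13 of 75 in KO under BMP4 (adjusted p = 2.42e-07), 37 of 594 in KO under SMADi (adjusted p = 1.68e-06, and 38 of 596 without the doubted library) and 25 of 547 in DATG under SMADi (adjusted p = 0.0104). In DATG under BMP4 they were 1 of 14 (adjusted p = 0.676).

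**Figure D1:**
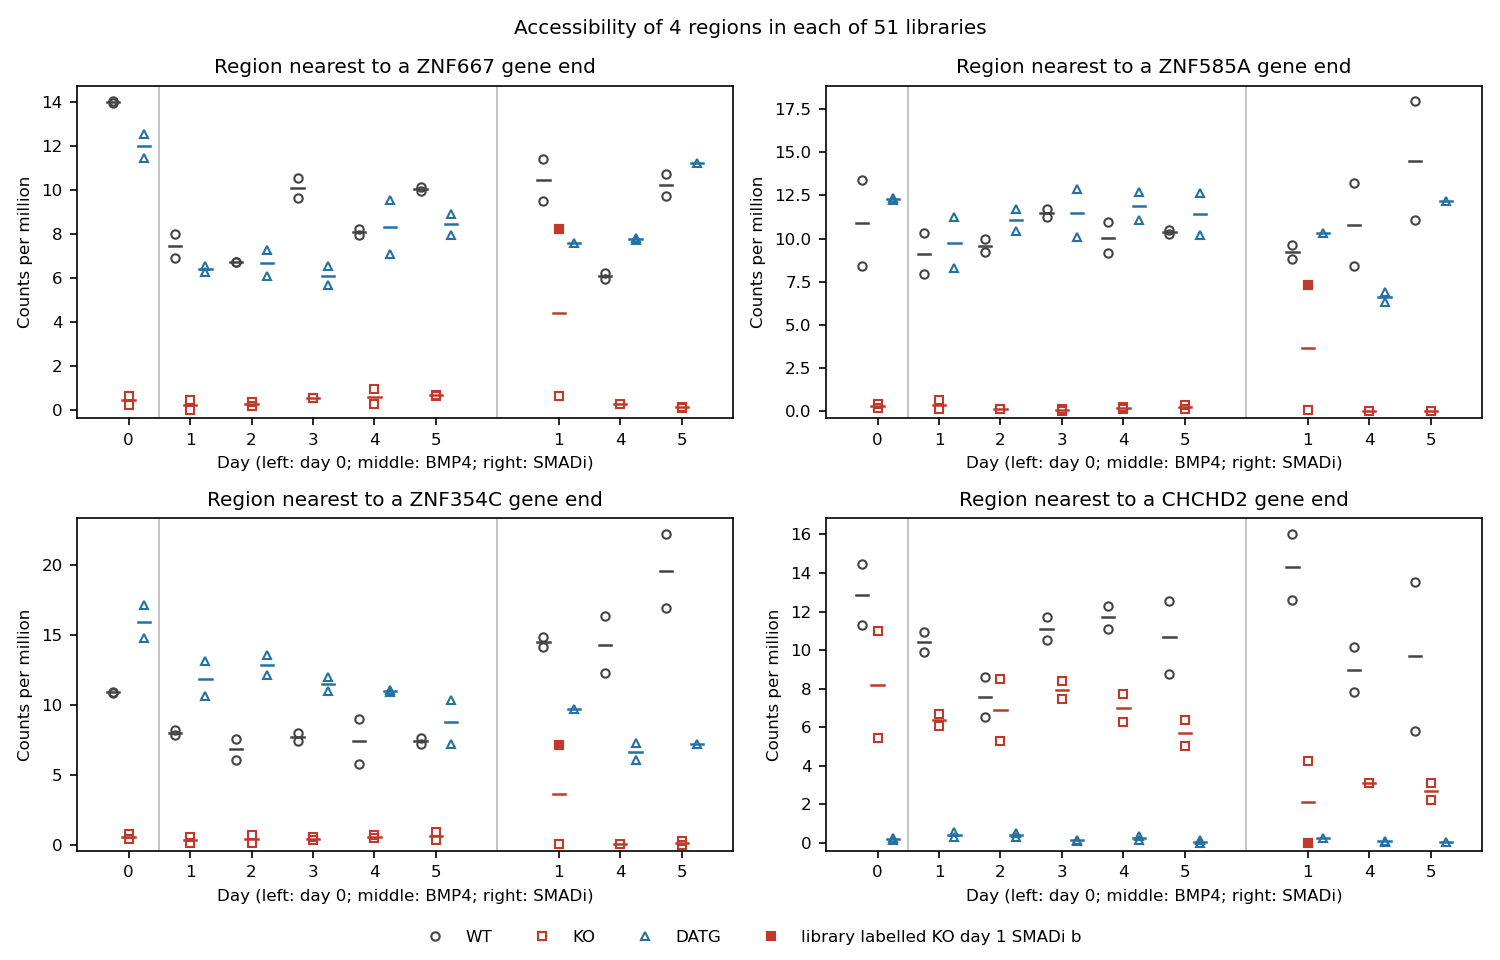
Accessibility in CPM (vertical axis) at the regions of ZNF667, ZNF585A, ZNF354C and CHCHD2 in every library, by genotype, treatment and day; points are libraries, bars are group means, and the filled square is the library labelled KO day 1 SMADi replicate b. KO was near 0 at the zinc-finger regions and DATG at CHCHD2 at every stage, except in that library, which had 106 counts at ZNF585A and 0 at CHCHD2.

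In WT cells under BMP4, many BMP targets opened and many pluripotency genes closed between day 1 and day 5, while mesoderm genes went both ways. With an estimated correlation these 2 list calls were lost (adjusted p = 0.225 and 0.309). Gene-linked accessibility rose at APLNR, the apelin receptor of nascent mesoderm (1.84 ± 0.18, SE, n = 2 per day), at the cardiac and lateral plate regulators HAND1 (0.60 ± 0.06) and GATA6 (0.47 ± 0.08), and at the simple-epithelium keratins KRT18 (0.95 ± 0.06) and KRT19 (0.97 ± 0.07). It fell at the pluripotency genes POU5F1 (−0.60 ± 0.11) and NANOG (−0.73 ± 0.16), at TBXT, the primitive streak factor (−0.71 ± 0.27), and at the Nodal antagonists LEFTY1 (−0.98 ± 0.10) and LEFTY2 (−0.84 ± 0.10). With only regions within 1 kb counted, KRT18 stood at −0.0158 and LEFTY2 at 0.30. Of 20 BMP targets 11 rose and 1 fell (13 and 1 adjusted over the list alone; adjusted p = 0.00466). The inhibitory SMAD genes SMAD7 (0.69 ± 0.06) and SMAD6 (0.63 ± 0.06) led, while DLX5 fell by 0.31 ± 0.07. Of 29 pluripotency genes 15 fell and 5 rose, as they did adjusted over the list alone (adjusted p = 0.00466). ESRG (−1.69 ± 0.13) and PRDM14 (−0.44 ± 0.07) fell, and LIN28A (0.32 ± 0.06) and PODXL (0.25 ± 0.06) rose.

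Over all genes in WT under BMP4, 14374 of 30194 were called, 7424 higher and 6950 lower. List counts near these shares are not particular to a list, and the other lists did not pass as a set. Among them 8 of 17 p53 targets rose and none fell, and 14 of 32 neuroectoderm genes fell and 5 rose. In the same way 8 of 15 endothelial and blood genes fell and 3 rose, and 6 of 15 Nodal and Activin targets fell and 2 rose (adjusted p = 0.119 each). The streak list had 6 higher and 6 lower of 22, with PDGFRA up (0.29 ± 0.07) and WNT8A down (−0.79 ± 0.09). The lateral plate list had 8 higher and 3 lower of 20, with MEF2C down (−0.91 ± 0.22). The amnion list had 7 higher and 2 lower of 25, with the stratified-epithelium factor TP63 down (−0.82 ± 0.28). The regions that opened most lay near CCNL1 (5.30 ± 0.30), LRRC55 (5.05 ± 0.32), ARHGAP26 (5.00 ± 0.29), FMOD (4.96 ± 0.30) and DNAH2 (4.87 ± 0.28). Regions that closed included those near SSTR1 (−3.30 ± 0.28), XIAP (−2.66 ± 0.30), LTN1 (−2.51 ± 0.26) and RYK (−2.33 ± 0.27). In all, 49643 of 142083 regions were called, 28777 higher and 20866 lower. Scaling by total counts moved the median over all regions to −0.17 and gave 22412 higher and 32058 lower (58.9% lower), so the balance of opening and closing depended on the scaling. Leaving out WT day 5 replicate b gave 31100 calls.

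Under BMP4 the KO line had more accessibility than WT at many pluripotency and neuroectoderm genes and less at several streak genes. Each of these 3 lists had adjusted p = 0.113 with an estimated correlation. As means over 5 days (n = 10 libraries per line), APLNR fell by 1.29 ± 0.09 (SE), the mesoderm factor MESP1 by 0.33 ± 0.04, HAND1 by 0.27 ± 0.03, GATA6 by 0.26 ± 0.04, KRT18 by 0.46 ± 0.03 and KRT19 by 0.42 ± 0.04. Higher genes included NANOG (0.31 ± 0.07), POU5F1 (0.17 ± 0.05), the growth factor gene FGF2 (0.33 ± 0.04), USP44 (0.31 ± 0.05), the neural factors SOX1 (0.22 ± 0.03), PAX6 (0.28 ± 0.04) and ZIC1 (0.29 ± 0.04), and SOX17 (0.12 ± 0.05). TBXT did not pass (0.19 ± 0.14). Of all 30194 genes 8009 were called, 3853 higher and 4156 lower. Of 32 neuroectoderm genes 19 were higher and 1 lower (adjusted p = 1e-06), the lower being NES, an intermediate filament gene (−0.08 ± 0.03). Of 29 pluripotency genes 15 were higher and none lower (adjusted p = 1.6e-05). Adjusted over the list alone these counts were 19 and 1, and 17 and 0.

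Further lists passed in KO under BMP4 with smaller shifts. Of 22 streak genes 9 were lower and 2 higher (9 and 3 adjusted over the list alone; adjusted p = 0.0085, and adjusted p = 0.113 with an estimated correlation). The higher were DLL1 (0.17 ± 0.03) and GSC (0.17 ± 0.05). Of 25 amnion and trophoblast genes 6 were lower and 2 higher (7 and 2 adjusted over the list alone; adjusted p = 0.0139, and adjusted p = 0.113 with an estimated correlation). The higher were KRT7 (0.17 ± 0.04) and DLX5 (0.12 ± 0.03). Of 20 BMP targets 8 were lower, among them MSX2 (−0.18 ± 0.03) and BAMBI (−0.20 ± 0.03), and 1 higher (8 and 1 adjusted over the list alone; adjusted p = 0.0326, and adjusted p = 0.293 with an estimated correlation). Of 42 HOX and CDX genes 14 were higher, among them HOXD3 (0.24 ± 0.05), and none lower (17 and 1 adjusted over the list alone; adjusted p = 0.0085, and adjusted p = 0.389 with an estimated correlation). Of 21 imprinted genes 5 were higher, among them GNAS (0.23 ± 0.04) and MEG3 (0.35 ± 0.06), and none lower (5 and 0 adjusted over the list alone; adjusted p = 0.0338, and adjusted p = 0.113 with an estimated correlation). Lists that did not pass were epithelial (3 higher and 4 lower of 16, adjusted p = 0.0752), lateral plate (0 and 6 of 20, 0.078), neural crest and placode (6 and 3 of 18, 0.157), and endothelial and blood (4 and 2 of 15, 0.24). Nor did mesenchyme and fibroblast (1 and 3 of 18, 0.259), p53 targets (0 and 1 of 17, 0.416), Nodal and Activin targets (2 and 5 of 15, 0.463), endoderm (3 and 4 of 17, 0.574), ribosomal protein genes (2 and 4 of 42, 0.574) and WNT targets (2 and 3 of 18, 0.883) pass.

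The KO difference covered 30494 regions under BMP4, 12923 higher and 17571 lower, and of the 2970 over 2-fold apart 2779 were lower. The strongest losses were near ZNF680 (−5.89 ± 0.28), ZNF585A (−5.62 ± 0.20), ZNF667 (−5.47 ± 0.19), ZNF354C (−3.88 ± 0.18) and ZNF229 (−2.21 ± 0.12). The strongest gains were near ABCA7 (2.21 ± 0.10), SLC25A42 (1.72 ± 0.12), CFLAR (1.54 ± 0.11), LOC124902053 (1.33 ± 0.09) and LOC124900867 (1.31 ± 0.12). ZNF680 had 0 counts in both KO libraries on day 2, at least 12.1-fold lower than WT. Called regions lay away from gene ends, with 18.4% of the higher and 14.9% of the lower ones near an end against 31.6% of tested regions (Fisher's exact p = 1.18e-275 for the higher). A DESeq2 Wald test called 18658 regions.

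DATG under BMP4 also had more accessibility than WT at several pluripotency and neuroectoderm genes and less at several streak genes, and with an estimated correlation these lists had adjusted p = 0.157, 0.19 and 0.19. APLNR fell by 0.76 ± 0.09 (SE, n = 10 libraries per line), MESP2 by 0.48 ± 0.09, HAND1 by 0.15 ± 0.03 and GATA6 by 0.14 ± 0.04. Genes ESRG (0.37 ± 0.06), NANOG (0.27 ± 0.08), USP44 (0.27 ± 0.05), LHX2 (0.14 ± 0.03), PAX6 (0.15 ± 0.05) and SOX1 (0.13 ± 0.03) were higher. Gene-linked calls numbered 3936 of 30194 genes, 1885 higher and 2051 lower. Of 29 pluripotency genes 8 were higher and none lower (11 and 0 adjusted over the list alone; adjusted p = 8.87e-06, and adjusted p = 0.157 with an estimated correlation). Of 32 neuroectoderm genes 14 were higher and none lower (16 and 0 adjusted over the list alone; adjusted p = 1.79e-05, and adjusted p = 0.19 with an estimated correlation). HOX and CDX genes were higher at 6 of 42, HOXD3 among them at 0.23 ± 0.05 (6 adjusted over the list alone; adjusted p = 0.00372, and adjusted p = 0.355 with an estimated correlation). Streak genes were lower at 7 and higher at 2 of 22 (8 and 3 adjusted over the list alone; adjusted p = 0.0132, and adjusted p = 0.19 with an estimated correlation). WNT8A was among the higher at 0.18 ± 0.04, and at −0.0154 with only regions within 1 kb counted. Of 17 p53 targets 3 were lower, among them the DNA repair gene XPC (−0.41 ± 0.08) and the cell cycle inhibitor CDKN1A (−0.54 ± 0.14), and none higher (5 and 1 adjusted over the list alone; adjusted p = 0.0425, and adjusted p = 0.157 with an estimated correlation). BMP targets had 3 lower, SMAD7 among them (−0.13 ± 0.03), and 1 higher of 20 (4 and 1 adjusted over the list alone; adjusted p = 0.0476, and adjusted p = 0.34 with an estimated correlation).

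DATG calls under BMP4 numbered 13247, 5849 higher and 7398 lower. The strongest losses were near CHCHD2 (−5.32 ± 0.19), PARK7 (−2.14 ± 0.12), PAPLN (−1.60 ± 0.13), CDH17 (−1.54 ± 0.10) and PRAF2 (−1.52 ± 0.12), and the strongest gains near PRRT1 (1.52 ± 0.09), ZBTB16 (1.51 ± 0.13) and CEBPZ (1.02 ± 0.12). KO and DATG themselves differed at 2610 regions, 738 higher in KO and 1872 lower. KO was higher at CHCHD2 (4.72 ± 0.22), PARK7 (2.20 ± 0.13), SLC25A42 (2.19 ± 0.13), PRAF2 (2.17 ± 0.12) and USP4 (2.06 ± 0.11). It was lower at ZNF680 (−6.49 ± 0.25), ZNF585A (−5.75 ± 0.20) and ZNF667 (−5.35 ± 0.19). Among all 30194 genes 800 were called, 276 higher in KO and 524 lower. Amnion and trophoblast genes were lower in KO than in DATG at 4 of 25, over all genes and adjusted over the list alone, among them the hormone subunit gene CGA (−1.81 ± 0.19) and KRT18 (−0.21 ± 0.03). The set call held with an estimated correlation (adjusted p = 0.000386, and adjusted p = 0.0275 with an estimated correlation). Imprinted genes also held (1 higher of 21, GNAS at 0.18 ± 0.04, and 4 adjusted over the list alone; adjusted p = 0.00494, and adjusted p = 0.0275 with an estimated correlation). Neuroectoderm genes did not (1 higher of 32, ZIC1 at 0.16 ± 0.05, and 2 adjusted over the list alone; adjusted p = 0.00494, and adjusted p = 0.53 with an estimated correlation). DESeq2 gave 4523 calls for DATG and 860 for KO against DATG.

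The BMP4 differences were small on day 1 and large on day 5. KO differed from WT at 78 regions on day 1 and 22517 on day 5, and DATG at 60 and 6622. With a library left out in turn the counts were 36 to 55 (lowest without KO replicate a) and 11553 to 19372 (lowest without WT replicate b) for KO. For DATG they were 29 to 37 (lowest without DATG replicate b) and 660 to 5024 (lowest without WT replicate b). Along the WT path from day 1 (0) to day 5 (1), WT stood at 0.387, 0.735 and 0.805 on days 2 to 4. KO stood at 0.192, 0.439, 0.462 and 0.603 on days 2 to 5, and DATG at 0.313, 0.488, 0.590 and 0.729. The mean difference from WT over the days was −0.257 for KO and −0.171 for DATG, with WT days 1 and 5 fixed by construction. The day 5 against day 1 change differed from that of WT at 2974 regions in KO, 1088 higher and 1886 lower, and at 108 in DATG, 33 higher and 75 lower. Scaling by total counts moved the lower share from 63.4% to 46.3% in KO and from 69.4% to 50% in DATG, so these calls have no firm overall direction. Their number was also unstable. For KO it went from 500 without KO day 5 replicate a to 4186 without KO day 5 replicate b, and for DATG from 9 without WT day 5 replicate b to 411 without DATG day 5 replicate a. DESeq2 gave 60 and 12. The KO interaction called 1964 of 30194 genes, 846 higher and 1118 lower. In it HAND1 was lower (−0.30 ± 0.09) and SOX1 (0.32 ± 0.09) and PAX6 (0.43 ± 0.14) were higher. Of its lists, 9 of 32 neuroectoderm genes were higher and none lower (13 and 0 adjusted over the list alone; adjusted p = 1.55e-07, and adjusted p = 0.0844 with an estimated correlation).

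**Figure D2:**
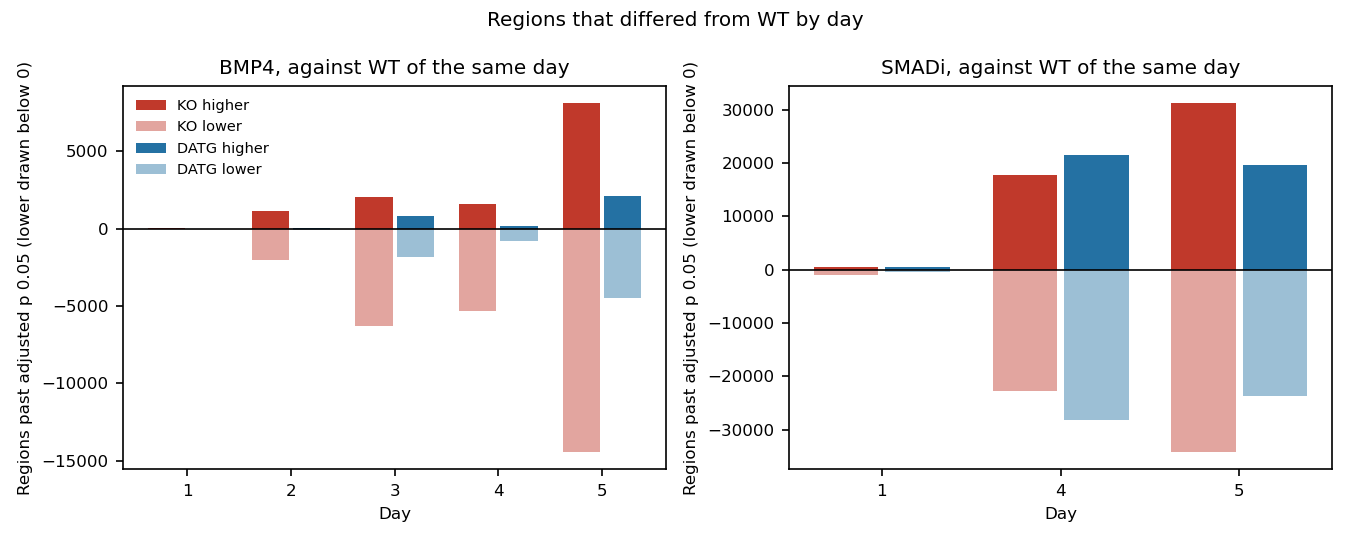
Regions called between each mutant line and WT (vertical axis, number of regions, higher and lower separately) on each day under BMP4 and SMADi. Under BMP4 the KO calls went from 78 on day 1 to 22517 on day 5, and under SMADi from 1449 on day 1 to 65290 on day 5.

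**Figure D3:**
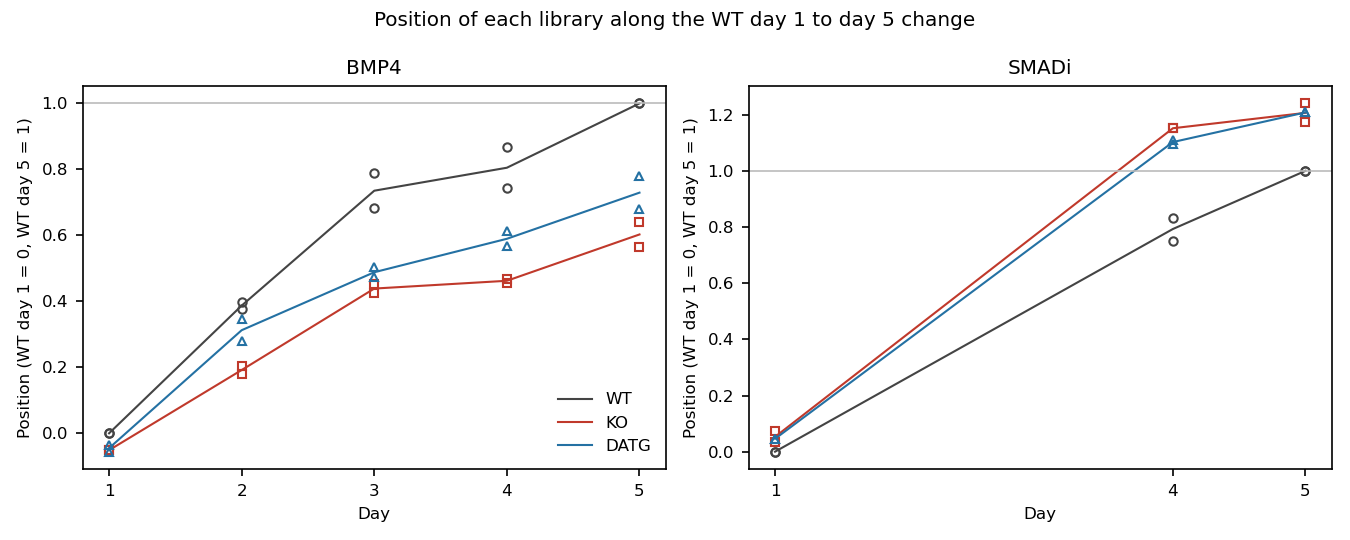
Position between WT day 1 (0) and WT day 5 (1), without unit, against day for each line under BMP4 and SMADi; lines join group means and open points are the lowest and highest library. The mutant lines lay below WT from day 2 under BMP4, with KO at 0.603 on day 5, and above WT on days 4 and 5 under SMADi, with KO at 1.21 on day 5.

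Under SMADi, WT cells lost accessibility at many pluripotency, epithelial and Nodal pathway genes between day 1 and day 5, and at many ribosomal protein genes of the control list. With an estimated correlation these 4 list calls were lost (adjusted p = 0.384, 0.111, 0.384 and 0.111). POU5F1 fell by 1.52 ± 0.20 (SE, n = 2 per day), the Nodal co-receptor gene CRIPTO by 1.08 ± 0.12, NODAL by 1.46 ± 0.12, NANOG by 0.78 ± 0.18, CDH1, the E-cadherin gene, by 0.88 ± 0.08 and the tight junction gene CLDN7 by 1.03 ± 0.12. The anterior neural factors SIX3 (0.82 ± 0.06) and HESX1 (0.99 ± 0.11) rose, and SOX1 and PAX6 did not pass (−0.07 ± 0.07 and 0.19 ± 0.09). For scale, 13811 of all 31439 genes were called, 7201 higher and 6610 lower. Epithelial genes fell at 10 of 16 and rose at 1, ELF3 at 0.34 ± 0.11 (10 and 3 adjusted over the list alone; adjusted p = 0.00371). Of 30 pluripotency genes 18 fell and 6 rose (19 and 6 adjusted over the list alone; adjusted p = 0.0154), the latter with KLF17 at 2.19 ± 0.20 and LIN28A at 0.53 ± 0.07. Of 15 Nodal and Activin targets 9 fell and 2 rose, GSC (0.67 ± 0.09) and CER1 (0.86 ± 0.20) (10 and 2 adjusted over the list alone; adjusted p = 0.0125). The control list moved as well: 16 of 41 ribosomal protein genes fell, such as RPL3 (−0.75 ± 0.07) and RPL13 (−0.74 ± 0.08), and 1 rose, the same numbers adjusted over the list alone (adjusted p = 0.00371).

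The neuroectoderm list did not pass as a set in WT under SMADi, with 11 higher and 3 lower of 32 (adjusted p = 0.321), SOX9 (−0.54 ± 0.08) and SOX11 (−0.60 ± 0.10) being lower. Nor did the imprinted list, with 7 higher and 3 lower of 21 (adjusted p = 0.0819), although MEG3 (1.93 ± 0.08) and DLK1 (1.28 ± 0.12), neighbours on chromosome 14, rose and IGF2R fell by 0.75 ± 0.11. With only regions within 1 kb counted, SOX9 stood at 0.13, SOX11 at 0.36, DLK1 at −0.0364 and RPL3 at 0.10. Regions near MTPN, KCNJ13, NCEH1 and WDR36 had 0 counts in both WT day 1 libraries and were at least 29.8-, 26.0-, 22.1- and 17.3-fold higher on day 5. A region near MAGI1 rose by 8.22 ± 0.50, and regions near GULP1 (−5.29 ± 0.52), PSMG3 (−5.03 ± 0.33), TMEM70 (−5.01 ± 0.39) and OBSL1 (−4.69 ± 0.33) fell. In all, 66416 of 162313 regions were called, 38724 higher and 27692 lower, and 43468 with a replicate block. Regions that rose were mostly away from gene ends (14.3% near an end against 27.6% of tested).

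Under SMADi both mutant lines had less accessibility than WT at many epithelial and pluripotency genes and more at several neural genes, as means over days. In KO, as a mean over days 1, 4 and 5 (n = 5 KO and 6 WT libraries), CLDN7 was lower by −1.56 ± 0.08 (SE), CDH1 by −0.72 ± 0.05, the pluripotency-associated gene DPPA2 by −1.16 ± 0.09, POU5F1 by −0.95 ± 0.13 and NANOG by −0.86 ± 0.11. Higher genes were the Notch effector HES5 (0.53 ± 0.06), the N-cadherin gene CDH2 (0.47 ± 0.05), SOX1 (0.33 ± 0.04), GATA6 (0.38 ± 0.06), and the WNT feedback inhibitors NKD1 (0.66 ± 0.06) and APCDD1 (0.57 ± 0.07). HESX1 (−0.51 ± 0.07) and SIX3 (−0.24 ± 0.04) were lower. These values include the library labelled KO day 1 SMADi replicate b. Calls covered 14147 of all 31439 genes, 6769 higher and 7378 lower. Of 16 epithelial genes 12 were lower and 1 higher, KRT19 at 0.13 ± 0.05 (12 and 1 adjusted over the list alone), and this set call held with an estimated correlation (adjusted p = 1.72e-08, and adjusted p = 0.0103 with an estimated correlation). Of 32 neuroectoderm genes 19 were higher and 3 lower (20 and 3 adjusted over the list alone; adjusted p = 0.000511). Of 30 pluripotency genes 15 were lower and 3 higher (15 and 4 adjusted over the list alone; adjusted p = 0.000714). Of 18 WNT targets 10 were higher and 3 lower (11 and 3 adjusted over the list alone; adjusted p = 0.0129). Of 20 BMP targets 11 were higher, such as ATOH8 (0.30 ± 0.04), and 3 lower, such as BMP7 (−0.43 ± 0.09) (11 and 3 adjusted over the list alone; adjusted p = 0.0496). Each of these 4 had adjusted p = 0.48 with an estimated correlation. Without the doubted library the BMP target list no longer passed (adjusted p = 0.0517), and neither did KRT19 (adjusted p = 0.0717). SOX2, at 0.14 ± 0.04, and HESX1 stood at −0.00455 and 0.0682 with only regions within 1 kb counted.

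DATG under SMADi (n = 4 DATG and 6 WT libraries) differed from WT in the same lists. CLDN7 was lower by −1.52 ± 0.09 (SE), CDH1 by −0.63 ± 0.05, DPPA2 by −1.08 ± 0.10, CRIPTO by −1.06 ± 0.09, NANOG by −0.90 ± 0.12 and POU5F1 by −0.78 ± 0.13. Genes HES5 (0.51 ± 0.06), NKD1 (0.48 ± 0.07), SP5 (0.39 ± 0.06), EMX2 (0.28 ± 0.05) and SOX1 (0.22 ± 0.04) were higher. HESX1 was lower by −0.35 ± 0.07, and stood at 0.0943 with only regions within 1 kb counted. Calls over all 31439 genes numbered 10732, 4778 higher and 5954 lower. Of 16 epithelial genes 11 were lower and none higher (12 and 1 adjusted over the list alone; adjusted p = 2.43e-07, and adjusted p = 0.0153 with an estimated correlation). Pluripotency genes were lower at 15 and higher at 3 of 30 (16 and 4 adjusted over the list alone; adjusted p = 0.000588), and neuroectoderm genes higher at 13 and lower at 2 of 32 (13 and 2 adjusted over the list alone; adjusted p = 0.00347). WNT targets were higher at 7 and lower at 2 of 18 (10 and 2 adjusted over the list alone; adjusted p = 0.0298) and BMP targets higher at 7 and lower at 3 of 20 (8 and 3 adjusted over the list alone; adjusted p = 0.0415). Each of these had adjusted p = 0.487 with an estimated correlation. No list passed for KO against DATG, with the lowest adjusted p at 0.0805.

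**Figure D4:**
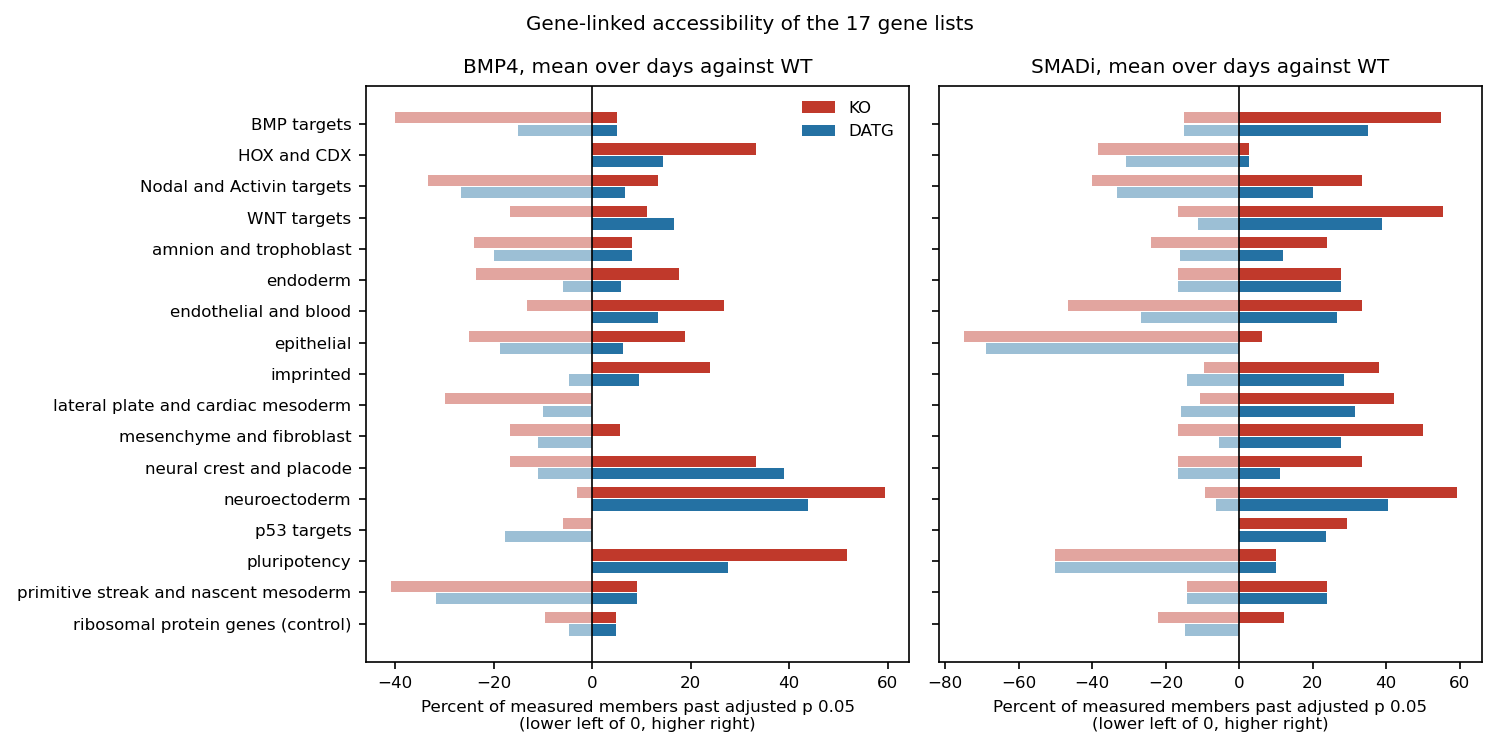
Percent of the measured members of each gene list past the threshold (horizontal axis), for each mutant line against WT as means over days. Panels are BMP4 and SMADi, with higher in dark and lower in pale bars. Under SMADi 12 of 16 epithelial genes were lower in KO and 11 of 16 in DATG; the SMADi KO values include the library labelled KO day 1 SMADi replicate b.

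Across regions, KO differed from WT at 64088 under SMADi, 28979 higher and 35109 lower, and at 55074 without the doubted library, 53339 of them called in both fits. Days with 2 libraries in both lines alone gave 39086. DATG differed at 46241, 17995 higher and 28246 lower (61.1% lower). A cyclic loess scaling gave 20655 higher and 18189 lower for DATG (46.8% lower), so which direction prevailed depended on the scaling. Among the largest KO gains were regions within GABRR2 (3.15 ± 0.38), SLC7A8 (2.87 ± 0.43) and SORL1 (2.66 ± 0.39) and near MTDH (2.81 ± 0.35). Without the doubted library SLC7A8 stood at 2.41 ± 0.88. In DATG, GABRR2 (2.97 ± 0.53), LRATD2 (2.75 ± 0.48), RNF220 (2.74 ± 0.30), SHISAL1 (2.68 ± 0.31) and FBXL14 (2.54 ± 0.64) led. ZNF585A had 0 counts in KO on days 4 and 5, at least 54.3- and 79.3-fold lower than WT. CHCHD2 (−6.54 ± 1.09) and C1QTNF4 (−4.69 ± 0.26) were lower in DATG, and ZNF117 and KCNJ15 had 0 counts in the DATG day 5 library, at least 49.9- and 15.7-fold lower than WT. Without the doubted library the CHCHD2 value in DATG was −6.54 ± 0.36, because spread is shared across groups. Near a gene end lay 40.3% of the KO-higher and 10.7% of the KO-lower regions, against 27.6% of tested regions, and 35.5% and 10.8% for DATG. The share of all counts near gene ends was 39.3% and 40.4% in the WT day 5 libraries, 47.0% and 45.5% in KO and 44.9% in DATG. On day 1 it was 41.5% and 41.8% in WT, 41.2% and 41.9% in KO and lower than these in DATG, so no rise was seen then. Without the doubted library 38.2% of the KO-higher and 10.5% of the KO-lower regions lay near a gene end.

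Only 97 regions differed between KO and DATG under SMADi, 71 higher in KO and 26 lower. With a library left out the count was 60 to 152, the lowest without KO day 1 replicate a and the highest without the doubted replicate b. Loess gave 52 calls and thinning 61. Exchanging genotypes within days gave as many calls in 2 of 27 groupings, the true one included, so chance was not excluded for this comparison. The groupings kept the doubted library as labelled and rested on 4 against 5 calls among 5000 regions. They were not repeated without that library. KO was higher near PARK7 (2.90 ± 0.32), SLC25A42 (2.89 ± 0.27), HSF5 (2.31 ± 0.30), LRRC14 (2.17 ± 0.27) and PRAF2 (1.85 ± 0.18). It was lower near ZNF835 (−2.04 ± 0.25), ZNF471 (−1.75 ± 0.16), EZHIP (−1.44 ± 0.24) and NR1I2 (−1.16 ± 0.20). Differences from WT were small on day 1, with 1449 regions in KO and 1020 in DATG, and large on day 4 (40400 and 49719) and day 5 (65290 and 43273). On day 1 the KO count was 304 without the doubted library, 263 of them shared, and the DATG count was 191 without WT replicate b. On day 5 the KO calls were 52.3% lower, and 64.9% lower with scaling by total counts, which moved the median over all regions to −0.16. On the WT path, KO stood at 1.15 on day 4 (1 library) and 1.21 on day 5 and DATG at 1.10 and 1.21 (1 library), against 0.793 for WT on day 4. The mean difference over days was 0.206 for KO and 0.188 for DATG.

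The change from day 1 to day 5 under SMADi differed from that of WT at 30710 regions in KO, 11156 higher and 19554 lower, and at 22518 in DATG, 8277 higher and 14241 lower. CLDN7 (−2.26 ± 0.19, SE) and CLDN4 (−1.01 ± 0.11) fell further in KO than in WT, and EMX2 (0.73 ± 0.10), HES5 (0.91 ± 0.13) and SOX1 (0.54 ± 0.09) rose more. The KO interaction called 8523 of 31439 genes, 3616 higher and 4907 lower, and the DATG interaction 6751, 2930 higher and 3821 lower. Epithelial genes were lower at 8 of 16 and higher at none in both interactions (for KO 8 and 0 adjusted over the list alone, adjusted p = 1.02e-06, and adjusted p = 0.0194 with an estimated correlation; for DATG 9 and 0 adjusted over the list alone, adjusted p = 1.28e-05, and adjusted p = 0.0355 with an estimated correlation). Neuroectoderm genes were higher at 16 and lower at 2 of 32 for KO, SIX3 and HESX1 being lower, HESX1 not without the doubted library (adjusted p = 0.0822) (18 and 2 adjusted over the list alone; adjusted p = 2.67e-06, and adjusted p = 0.414 with an estimated correlation) and higher at 18 and lower at 1 of 32 for DATG (21 and 1 adjusted over the list alone; adjusted p = 1.61e-09, and adjusted p = 0.291 with an estimated correlation). The KO count was 21113 without the doubted library and 19528 without KO day 1 replicate a, and the DATG count was 13114 without WT day 1 replicate b and 35782 without WT day 5 replicate b. DESeq2 gave 17929 and 8382, thinning 19127 and 11202, and a replicate block 10571 for DATG. In KO 63.7% of calls were lower, 79.2% with total counts and 49.6% with loess, and in DATG 63.2%, 49.7% with loess.

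KO and DATG differed from WT in similar ways during differentiation. Across regions, which are not independent replicates, KO and DATG log2 fold changes against WT had a Pearson correlation of 0.418 at day 0, 0.805 under BMP4 and 0.924 under SMADi. Simulated unchanged groups against the same WT libraries gave 0.492, 0.466 and 0.423. The covariance above the simulated value was 0.00405, 0.0484 and 0.328. With WT replicate a for KO and b for DATG the correlation was 0.650 under BMP4 and 0.828 under SMADi, where unchanged groups gave −0.00337 and 0.00118. At day 0 the WT libraries were not split this way, and the simulated value was above the observed one. There 3 higher and 5 lower regions were called in both lines. Under BMP4 4893 higher and 6415 lower regions were called in both, and under SMADi 14689 and 24789. Both lines were set against the same WT libraries, which raises such overlaps. Without the doubted library the SMADi correlation was 0.914 and the shared calls 12581 and 22991. Median log2 fold changes per chromosome lay near 0, the largest being −0.06 on chromosome 22 for KO against DATG at day 0. A single region, 2111 bp from ZNF610, had at most 1 count in every DATG library under SMADi against a WT mean of 107, and no other comparison as labelled had such a region. With at most 3 counts allowed the numbers changed, to 3 in KO and 2 in DATG at day 0, 2 and 1 under BMP4, and 6 and 12 under SMADi. Without the doubted library, KO under SMADi had 14 regions with at most 3 counts and 1 with at most 1 count. In the other direction 19 regions present in KO and 14 present in DATG had at most 3 counts in every WT library under SMADi.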

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

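The tests in this part were written down before they were run but after the patterns had been seen, and their bounds were not changed afterwards. The comparisons that put results here were the 4 interactions, in which the change from day 1 to day 5 differed between a mutant line and WT. Under BMP4 these were 2974 regions for KO and 108 for DATG, and under SMADi 30710 for KO and 22518 for DATG. Neither BMP4 number was stable, since the DESeq2 Wald test gave 60 and 12.

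Under BMP4 the mutant lines stood behind WT on the WT path. Library depth was excluded, because KO day 5 stood at 0.600 after thinning to equal depth and 0.603 before, and DATG day 5 at 0.714 and 0.729. The bound written against weaker signal over background was met in KO, with a KO to WT spread ratio of 1.01 on day 5 at steady regions. Counting noise also enters this spread, so the ratio does not exclude weaker signal, and DATG was not tested. Against the best matching WT day, day 2, KO day 5 still had 11457 calls, 50.9% of the 22517 against WT day 5. This passed the bound written against a plain delay but does not exclude one. KO day 5 stood between WT day 2 (0.387) and WT day 3 (0.735), so a delayed line need not match any sampled day. No count between neighbouring WT days was set beside it. Whether the edit or the history of each line lies behind the difference was not tested, because the labels give no independent clones.

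Under SMADi the mutant lines stood ahead of WT on the WT path, and depth as the whole cause needed a DATG lead on day 4 under 0.1 after thinning, and the lead was 0.307, against 0.310 before. Thinned libraries stood at 1.11 and 1.09 in DATG and 0.759 and 0.829 in WT, which excludes depth as the whole cause, although replicate b missed the bound written for this. A WT culture mixed from early and late cells could not be told from other causes, with 3.53% of regions highest in WT day 4 and 0.508% lowest. Faster passage along the WT path fitted its bound: 91.0% of 7460 regions over 2-fold apart on day 4 moved the same way in WT from day 4 to day 5. With the letters exchanged, which uses the shallow WT day 5 library, it was 71.3%, under the bound, so this is not settled. No share over all regions was set beside these shares. Single genes went both ways. POU5F1 fell in WT and was lower in both mutant lines, while SIX3 and HESX1 rose in WT but were lower in KO.

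Genotypes were also exchanged among libraries within days, and the number of calls among 5000 sampled regions was counted. Under BMP4 the true grouping was the only 1 of 100 groupings to reach its count in each comparison. Real and highest other counts were 1139 and 575 for KO, 475 and 90 for DATG, and 118 and 34 for KO against DATG. A chance split of these libraries was therefore excluded. Chance between cultures was not tested, because the libraries of a pair may be technical replicates. Under SMADi the true grouping was the only 1 of 100 to reach its count for KO, with 2007 calls against at most 1881 in the others. For DATG 2 of 54 reached it, the true one included, and the other gave more calls, 1507 against 1424. Both shares met the bound written for this, but other groupings gave about as many calls. A grouping that exchanges only day 1 libraries, where the lines differed little from WT, keeps the true lines on days 4 and 5. Near ties can therefore arise without chance, and which groupings gave them was not recorded. The near ties do not decide the question, so chance was not firmly excluded. For KO against DATG under SMADi, with 2 of 27 groupings and 4 calls against 5, chance was not excluded. The SMADi groupings kept the doubted library as labelled and were not repeated without it.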

How the results depend on the processing

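Of 266 region counts under other settings, 191 stayed within 1.5 times the main value, and of 190 with a library left out 119 did. Of 880 named region results 869 kept their call. Of 212 list results 133 were kept, 6 of 53 of them with an estimated correlation, and of 393 list gene results 330 were. Changed counts follow, and the cause was not tested. Depth limits the counts: thinned libraries hold fewer reads by construction. Motif tests and GC checks were not run.

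With the DESeq2 Wald test the BMP4 counts were 18658 (KO), 4523 (DATG), 860 (KO against DATG), 29099 (WT day 5 against day 1) and 60 and 12 (interactions). The SMADi interactions were 17929 and 8382, and day 0 gave 19, 13 and 38. Thinning, chosen after seeing the data, gave 18590, 5650, 1060, 28889, 189 and 12 under BMP4. It gave 61 for KO against DATG and 19127 and 11202 for the interactions under SMADi, and 54 (DATG) and 205 (KO against DATG) at day 0. Loess gave 52 for SMADi KO against DATG and 64 for day 0 DATG. Also chosen after seeing the data, days 1 to 4 under BMP4 gave 18002, 5654 and 1213, and SMADi days with 2 libraries gave 39086 for KO. The effect correlation at day 0 was 0.365 at regions at or above the median CPM. With WT replicate a for KO and b for DATG it was 0.650 under BMP4 and 0.828 under SMADi, where no WT library is shared by construction.

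With the replicate letter as a block within each day (replicate block), WT day 5 against day 1 under SMADi gave 43468, its DATG interaction 10571 and day 0 DATG 123. Letters did not pair libraries, with residual correlations from −0.127 to 0.156.

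With only regions within 1 kb, signs reversed under BMP4 for WNT8A in DATG (−0.0154), and in WT for KRT18 (−0.0158) and LEFTY2 (0.30). Under SMADi they reversed for SOX2 (−0.00455) and HESX1 (0.0682) in KO, HESX1 in DATG (0.0943), and in WT SOX9 (0.13), SOX11 (0.36), DLK1 (−0.0364), NAP1L5 (0.20) and RPL3 (0.10).

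With a library left out, day 0 counts ranged over 41 to 183 (KO), 31 to 278 (DATG) and 123 to 261 (KO against DATG). Under BMP4 they were 1666 to 2849 (KO against DATG), 31100 to 39323 (WT day 5 against day 1), and 500 to 4186 and 9 to 411 (interactions). Single days gave for KO 36 to 55, 787 to 1726, 1915 to 7376, 1710 to 4273 and 11553 to 19372, and for DATG 29 to 37, 22 to 158, 83 to 2402, 24 to 652 and 660 to 5024. Under SMADi they were 60 to 152 (KO against DATG), 19528 to 35904 and 13114 to 35782 (interactions), 304 to 443 and 191 to 264 (day 1, KO and DATG) and 31093 to 37992 (day 4, DATG).

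Scaling also moved the balance of directions. Loess moved the lower share of BMP4 DATG calls from 66.4% to 53.5% on day 2 and from 80.2% to 42.1% on day 4, and of SMADi day 1 calls from 68.5% to 58.1% in KO. Total counts moved BMP4 DATG day 5 from 67.7% to 56.9% and SMADi DATG day 1 from 51.7% to 62.5% (62.8% with loess).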

Other observations

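The interactions held further gene lists, among them the control list. Under SMADi, ribosomal protein genes were higher at 6 and lower at 1 of 41 for KO (4 and 1 adjusted over the list alone; adjusted p = 0.036, and adjusted p = 0.23 with an estimated correlation). BMP targets were higher at 6 and lower at 1 of 20 (10 and 1 adjusted over the list alone; adjusted p = 0.036, and adjusted p = 0.581 with an estimated correlation). Without the doubted library these lists had adjusted p = 0.0241 and 0.0487. Also under SMADi, lateral plate genes were higher at 7 and lower at 1 of 19 for KO, as they were adjusted over the list alone (adjusted p = 0.011, and adjusted p = 0.581 with an estimated correlation). For DATG they were higher at 8 and lower at none (9 and 0 adjusted over the list alone; adjusted p = 0.000112, and adjusted p = 0.409 with an estimated correlation). Under BMP4, neural crest and placode genes were higher at 3 of 18 in the KO interaction and lower at none (6 and 0 adjusted over the list alone; adjusted p = 0.00156, and adjusted p = 0.0739 with an estimated correlation).

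The 3 tests of the doubted library were chosen only after its result had been seen, and the tests of the closed regions before they were run but after the regions had been seen. In the library labelled KO day 1 SMADi replicate b, ZNF667, ZNF585A and ZNF354C had 119, 106 and 104 counts and CHCHD2 had 0. KO replicate a had 8, 1, 1 and 54 at the same regions, and DATG replicate a had 91, 124, 117 and 3. A wrong line label fitted, with a position of 0.871 from KO (0) to DATG (1) at regions called under BMP4 and 0.840 at regions called at day 0. Positions are relative to the mean of each line and day, so groups of 1 library, and KO replicate a here, lie at 0 or 1 by construction. A mixture of KO and DATG cells could not be told apart from this, with a mean linear position of 0.959. It was 1.04 over 27 regions higher in KO, outside the mixture range, and 0.877 over 15 higher in DATG, inside it.

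A second copy of the DATG library was excluded by a chi-square per degree of freedom of 2.72. Over all regions the library was nearer KO replicate a, at 1.77. Only 97 of 162313 regions were called between KO and DATG under SMADi. This distance therefore mostly covers regions not called between the lines and does not decide the label. At ZNF667, ZNF585A, ZNF354C and CHCHD2 no held library was out of place the other way. The library was kept as labelled. Without it the SMADi KO interaction had 21113 calls, 19954 of them shared, and KO against DATG had 152. The KO day 1 count fell from 1449 to 304, and leaving out replicate a instead gave 443. Over SMADi days the KO position difference was 0.213 without it.

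Regions taken as closed in 1 mutant line at every stage had mostly unchanged surroundings beyond 2 kb. Loss of DNA copies over most of 2 to 100 kb at most of these regions was excluded, because 379 other regions there had a median log2 fold change of −0.00045. Nearer by, 10 regions up to 2 kb away from 7 of the 24 closed regions had a median of −2.15. The quartiles were −3.65 and −1.03, so the lower accessibility was mostly not limited to the counted region there. A short sequence change inside the counted region is not excluded, because it could lower nearby regions too. The median pools the 10 regions, so it does not speak for each of the 7. Nothing was measured up to 2 kb away from the other closed regions. A smaller loss of DNA, or a loss at a few of them, stays open, and whether these regions follow from the edits or from the history of each line was not tested.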
